A study of Mus musculus with 19 samples.

How the data were processed

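The series measured RNA from TuBo cells, a line cloned from a mammary carcinoma of a BALB-neuT mouse, which carries the activated rat ErbB2 oncogene. Per the labels, cells were grown either as an adherent layer in DMEM with 20% fetal calf serum or as mammospheres, floating spheres formed in serum-free medium. Per the labels, the sphere medium held bFGF at 20 ng/ml, EGF at 20 ng/ml, insulin at 5 ug/ml and 0.4% BSA, and spheres were collected after 7 days and passaged up to 3 times (P1, P2 and P3). Per the labels, RNA was extracted with a Mirvana kit, and 100 ng was amplified, labelled with biotin and hybridized to Affymetrix mouse exon arrays. The titles gave each array a group and an experiment number between 1 and 6, and 19 arrays were used: 6 adherent, 6 P1, 3 P2 and 4 P3.

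The deposited values were log2 signals, with 1 value per gene-level row and array. Per the submitters' processing notes, they came from Affymetrix Expression Console with RMA, whose versions were not given in the sources used here. The series text also gives sketch quantile normalization, but the deposited columns did not share 1 distribution, as described in the results. The series text further describes an exon-level splicing comparison with MiDAS that kept events shared by the 3 passages against adherent cells, and exon-level signals were not analysed here because the table used was at gene level. The number of arrays limits the precision.

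The table held 23238 rows, of which 14939 carried 1 gene symbol, 989 carried several and 7310 carried none. Of the rows without a symbol, 6577 lay in a separate low range of identifiers. Symbols were compared by gene number with the RefSeq table of the GRCm38.p6 assembly, which matched 14884 rows and changed 0 symbols. No genome build was given in the sources used here, so no positions are printed. All rows entered the gene tests, and list tests used 1 row per symbol, the row with the highest mean, which left 14807 genes. A gene with several rows, of which there were 131, was reported from the row with the highest mean.

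Each row was fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 19 arrays and moderated standard errors. The fit used 1 residual variance per row, shared by all groups. Where adherent arrays vary more than sphere arrays, this may make the errors of P1 and P3 against adherent cells too small. P values were adjusted over all rows of a contrast by the Benjamini-Hochberg method, and a row was called at an adjusted p under 0.05. Each passage was compared with adherent cells, and the passages were compared with each other. Errors given as SE come from this fit, and errors given as SD are between the arrays of a group. The labels do not say whether the experiments were separate cultures, so the p values measure only the spread between these arrays, which may be technical.

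The choice of the deposited values for the tests, the alternatives of block, scaling, filter and variance model, the gene lists and the rule for named genes were fixed before the data were examined. The rule named, for each passage against adherent cells, up to 10 genes with the largest increase and 10 with the largest decrease among called rows with exactly 1 symbol whose arrays did not overlap between the groups, and 5 of each for passages against each other. From each list it named up to 4 called members with the largest change, or up to 2 members with the smallest p where none was called. Erbb2, Slc7a11, Tenm4, Cd44, Itga6, Krt14, Vim and Cdh1 were always reported. Cd24a, Ly6a and Krt8 had no row with only their own symbol. Quantile normalization of the deposited values between arrays was fixed as an alternative, while applying the naming rule to the quantile-normalized values as well was chosen after the values were seen. From the genes so named, those with the largest changes, the clearest calls or a use as an example of a list are given in the results.

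A set of 33 gene lists of pathways and cell type markers, written from general knowledge before the data were examined, was tested in the 3 passages, which made 99 tests. The lists held 702 members, of which 585 were measured. The test was camera from limma, which compares the mean moderated t statistic of the members with that of the other genes. It used a preset correlation between genes of 0.01, and p values were adjusted over the 99 tests. The same test with the correlation estimated within each list, and the rotation test fry from limma, were run as alternatives. Camera asks whether members moved more than other genes, so a list median is given beside each test. Members were also counted after adjusting their p values over the list alone. A mean over the members was taken on each array and compared between groups with an exact permutation test, which was chosen after the data were seen.

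A pair of groups was treated as paired by experiment number where the residual correlation of arrays with the same number was over 0.1 in every pair, which was decided before any calls were compared. Adherent and P2 arrays met this in 3 of 3 pairs, with correlations between 0.18 and 0.56, so the value with the experiment number as a block is given for P2 where it changed a call. The other pairs of groups did not meet it.

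The alternatives were the experiment number as a fixed block and as a random block (duplicateCorrelation with statmod 1.5.0), quantile normalization, centring each array on its median, rows above the 25th or the 50th percentile of mean signal, 1 row per gene, the row with the largest variance, a variance trend with robust moderation, array quality weights (arrayWeights), only the arrays of the 2 groups compared, an adjusted p under 0.01, and each array left out in turn. The interquartile range of each array as a covariate, adherent replicates 1 and 3 left out together, and quantile normalization joined with the block, the weights, the estimated correlation or left-out arrays were chosen after the data were seen. Arrays were also regrouped at random into groups of the same sizes, at most 100 times per contrast. Overlap between passages, and later also the counts, were compared with 100 simulations in which the passages shared adherent arrays and no gene differed. The simulation first drew arrays with replacement. Drawing random combinations of the arrays' deviations was added after the first values were seen, and both are given. Simulations of quantile-normalized values were not normalized again, so unlike the real arrays the simulated ones could differ in distribution. Drawing with replacement could repeat an array within a group, which lowers its spread.

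The code was tested on simulated data with 23238 rows, the same group sizes and 20 draws, in which 100 rows were changed 2-fold and 100 were changed 4-fold. In P1 against adherent 56.5% of the 2-fold and 93.6% of the 4-fold changes were called, in P2 39.4% and 87.4%, and in P3 48.5% and 90.4%. False calls were 5.25% ± 1.84 (SD, n = 20 draws) of all calls in P1, 5.86% ± 2.21 in P2 and 4.86% ± 2.16 in P3. A simulated hypoxia list shifted by -0.5 was called with an adjusted p of 4.1e-07, and 0 of the 98 other list tests were called. The simulation had independent rows and equal spread in all groups, which the real arrays did not have.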

Results

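Gene-level RNA signals were measured in TuBo cells, a mouse mammary carcinoma line driven by activated rat ErbB2, grown as an adherent layer or as mammospheres over 3 passages. The 19 arrays fell into 4 groups, with n = 6 adherent, n = 6 P1, n = 3 P2 and n = 4 P3. Growth as floating spheres in serum-free medium is a standard assay for cells with stem-like properties, and the comparisons below ask which genes differ between spheres of each passage and adherent cells. All values are log2 signals, so a difference of 1 is a 2-fold change.

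Adherent arrays varied more among themselves than sphere arrays did. The interquartile range of the signals averaged 2.93 ± 0.57 (SD, n = 6) in adherent arrays and ran from 2.06 to 3.49. It averaged 3.14 ± 0.25 (SD, n = 6) in P1, 3.27 ± 0.15 (SD, n = 3) in P2 and 3.19 ± 0.29 (SD, n = 4) in P3. The mean Pearson correlation of an array with the others of its group lay between 0.890 and 0.947 in adherent cells, between 0.966 and 0.979 in P1, between 0.978 and 0.983 in P2 and between 0.971 and 0.974 in P3. Array medians ran from 6.95 to 7.58, and no column was identical to another. Because the arrays differed in spread, values are given as deposited and, where named so, after quantile normalization between arrays.

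**Figure D1:**
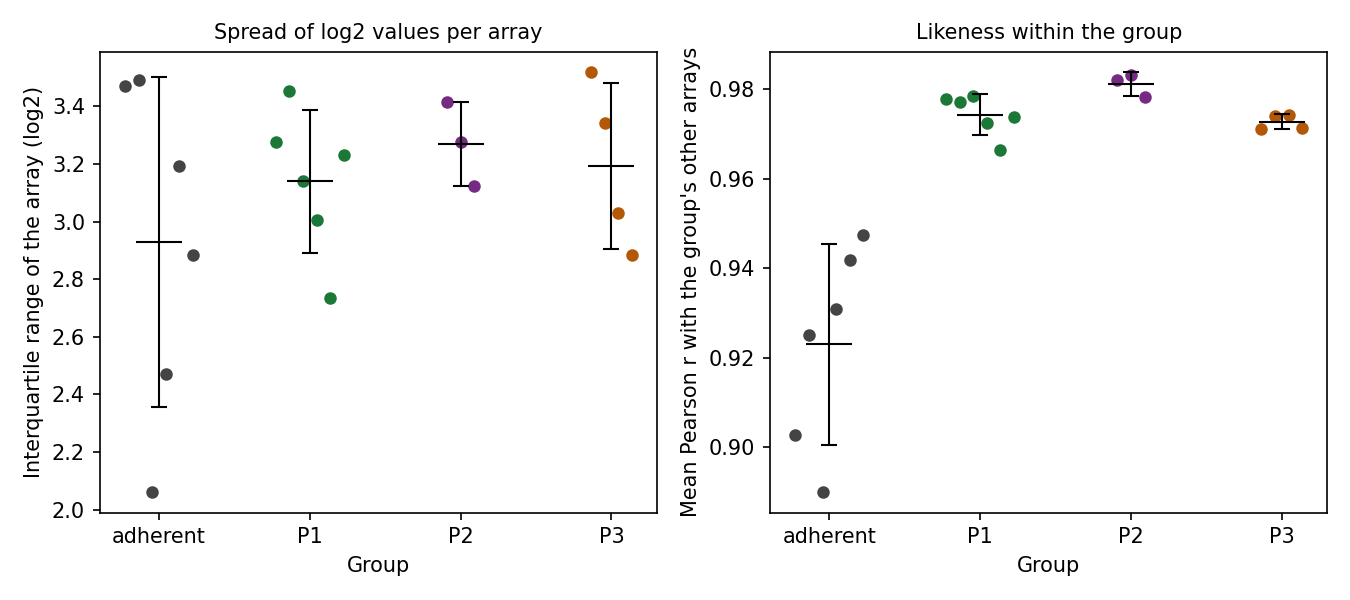
Interquartile range of the log2 signals of each array (left) and mean Pearson correlation of each array with the other arrays of its group (right), for adherent, P1, P2 and P3; points are arrays and bars are the mean ± SD. Adherent arrays had the widest range of both, from 2.06 to 3.49 for the interquartile range and from 0.890 to 0.947 for the correlation.

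First-passage spheres had less Bnip3 and Smtnl2 and more Zdhhc23 than adherent cells. Bnip3, a mitophagy receptor induced by low oxygen (row 6971987), fell from 10.58 ± 0.42 to 9.23 ± 0.21 (SD, n = 6 each), a change of -1.35 (SE 0.18, adjusted p = 0.00943). Smtnl2, a smoothelin-like muscle protein (row 6789540), fell from 8.30 ± 0.51 to 7.07 ± 0.23, a change of -1.23 (SE 0.19, adjusted p = 0.0289). Zdhhc23, a palmitoyltransferase (row 6845911), rose from 7.69 ± 0.37 to 9.05 ± 0.25, a change of 1.36 (SE 0.19, adjusted p = 0.0139). In all 3 genes, no P1 array overlapped an adherent array, which the rule for naming the largest changes required, so it is not added support. With only the 2 groups in the fit the adjusted p was 0.120 for Bnip3, 0.434 for Smtnl2 and 0.120 for Zdhhc23. Over all alternatives other than single arrays left out, it ran from 0.00109 to 0.120 for Bnip3 and from 0.000275 to 0.434 for Smtnl2. For Zdhhc23 it ran from 0.00109 to 0.120. The call of Zdhhc23 was lost without P1 array 1, 3 or 4 (adjusted p = 0.0528, 0.0556 and 0.0592). That of Smtnl2 was lost without adherent array 2, 5 or 6 (0.050, 0.104 and 0.0549) and without P1 array 1, 2, 3, 4 or 5 (0.126, 0.0600, 0.126, 0.0680 and 0.0696).

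In total 4 rows passed an adjusted p of 0.05 between P1 and adherent cells, 1 higher and 3 lower, the fourth being a row with 2 symbols that fell by 0.81 (adjusted p = 0.00943). Of these, 3 changed at least 2-fold. At an unadjusted p under 0.05 the limma fit gave 1886 rows, 1256 higher and 630 lower. The count of 4 became 138 without adherent array 1, 10 without adherent array 3, 9 without adherent array 4, and 2 without P1 array 1, 3 or 4. The count of 3 with a 2-fold change became 94, 9 and 8 without the same adherent arrays, 1 without P1 array 1, 3 or 4, and 5 without P1 array 6. Arrays did not overlap in 23 rows higher and 33 rows lower in P1, 0.241% of rows, where chance alone gives 0.216%. After quantile normalization 363 rows passed, 210 higher and 153 lower, and 106 of them changed at least 2-fold. That count became 1078 without adherent array 1 and 202 without adherent array 5. It became 140, 158, 152, 185 and 174 without P1 arrays 1, 2, 3, 4 and 6. Simulations in which no gene differed gave 363 or more rows in 12 of 100, and in 19 of 100 with arrays drawn with replacement.

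After quantile normalization, the called genes lower in P1 spheres included Ccn1, Ndrg1, Lrp1 and Muc1. Ccn1, a matricellular protein and classic target of YAP, fell from 11.49 ± 0.56 to 8.66 ± 0.74 (SD, n = 6 each), which was 7.08-fold lower (-2.82, SE 0.38, adjusted p = 0.00182). Its relative Ccn2 fell by 2.01 (SE 0.43, adjusted p = 0.0274). Muc1, a transmembrane mucin, fell from 9.57 ± 0.28 to 7.42 ± 0.47 (-2.15, SE 0.26, adjusted p = 0.000941). Ndrg1, which low oxygen induces, fell from 11.34 ± 0.43 to 8.81 ± 0.88 and was 5.77-fold lower (adjusted p = 0.00477), and the phosphodiesterase Pde2a fell by 1.79 (SE 0.20, adjusted p = 0.000502). The endocytic receptor Lrp1 (-2.20, adjusted p = 0.0307), the protease Prss22 (-2.14, 0.00285), the clock repressor Bhlhe41 (-1.95, 0.00264) and the adducin Add3 (-1.59, 0.00404) fell too. As deposited none of these passed, with adjusted p values of 0.112 for Ccn1, 0.0762 for Muc1 and 0.106 for Pde2a. Over the alternatives the adjusted p ran from 0.00182 to 0.513 for Ccn1, from 0.000535 to 0.219 for Muc1, from 5.91e-05 to 0.513 for Ndrg1 and from 0.000502 to 0.527 for Pde2a.

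Among the named genes called higher in P1 after quantile normalization, the cytokine gene Csf3, which encodes G-CSF, changed most. Csf3 rose from 10.15 ± 0.83 to 12.01 ± 0.24 (SD, n = 6 each), a change of 1.86 (SE 0.29, adjusted p = 0.00419). The tight junction gene Cldn1 rose from 10.45 ± 0.57 to 11.79 ± 0.27 (1.35, SE 0.22, adjusted p = 0.00475). Ddias, an anti-apoptotic gene of the DNA damage response, rose by 1.59 (adjusted p = 0.00404), the Wnt receptor Fzd3 by 1.47 (0.00588), Cdr2 by 1.43 (0.0152) and the bHLH-PAS factor Arnt2 by 1.29 (0.00585). Nhp2, a small nucleolar RNA-binding protein, rose by 1.27 (0.0125), Faxc by 1.25 (0.00723) and the protocadherin Pcdhb17 by 1.24 (0.019). The deposited change of Csf3 was 2.11 with an adjusted p of 0.0762, and over the alternatives its adjusted p ran from 0.00368 to 0.513. That of Cldn1 ran from 0.00475 to 0.885, and that of Ddias from 0.00239 to 0.744.

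In second-passage spheres, the largest called difference from adherent cells was in Clca2, a regulator of chloride channels. After quantile normalization Clca2 rose from 6.13 ± 0.39 (SD, n = 6) to 8.55 ± 0.45 (SD, n = 3), a change of 2.42 (SE 0.36, adjusted p = 0.0123). As deposited the change was 2.46 (SE 0.38, adjusted p = 0.107), and over the alternatives the adjusted p ran from 0.00152 to 0.383. On the same scale Csf3 rose by 2.00 (SE 0.35, adjusted p = 0.0314), Zdhhc23 by 1.29 (SE 0.22, 0.0314), Eps8, an adaptor of EGF receptor signalling, by 1.32 (0.0204), and the mitochondrial myosin Myo19 by 1.11 (0.0123). The inhibitory Smad gene Smad7 fell from 10.28 ± 0.27 to 9.13 ± 0.21 (-1.16, SE 0.16, adjusted p = 0.00592). Decreases were also called in Pde2a (-1.60, SE 0.25, adjusted p = 0.0123), Muc1 (-1.66, SE 0.32, 0.044), Ccn1 (-2.39, SE 0.47, 0.0454), the actin regulator Coro6 (-1.25, 0.0361) and the transcription factor gene Glis2 (-1.14, 0.0123). Over the alternatives the adjusted p ran from 0.00503 to 0.982 for Smad7 and from 0.00406 to 0.982 for Pde2a.

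As deposited, limma called 0 rows between P2 and adherent cells, with a smallest adjusted p of 0.107, and gave 1684 rows at an unadjusted p under 0.05, 1182 higher and 502 lower. The count became 27 without adherent array 1 and 1 without adherent array 6. With the experiment number as a block, 1 row passed: Ndrg1, which fell by 2.00 (SE 0.20, adjusted p = 0.00641), against -2.13 (SE 0.57, adjusted p = 0.451) without the block. Arrays did not overlap in 335 rows higher and 191 rows lower, 2.26% of rows against 2.38% from chance. After quantile normalization 41 rows passed, 22 higher and 19 lower. That count became 339 without adherent array 1, 16 without adherent array 5, and 3, 5 and 2 without P2 arrays 1, 2 and 4. With the block it was 42, and Ndrg1, called with the block as deposited, was not among the 41.

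Third-passage spheres had more Clca2, Trpv3 and Pgap6 and less Bnip3 than adherent cells. Clca2 (row 6910142) rose from 6.17 ± 0.46 (SD, n = 6) to 8.37 ± 0.55 (SD, n = 4), a change of 2.20 (SE 0.35, adjusted p = 0.0356). Trpv3, a warmth-activated cation channel of epithelia (row 6782294), rose from 6.50 ± 0.34 to 8.61 ± 0.31 (2.11, SE 0.31, adjusted p = 0.0209). Pgap6, a phospholipase that trims GPI-anchored proteins (row 6849432), rose from 7.15 ± 0.29 to 8.46 ± 0.20 (1.31, SE 0.15, adjusted p = 0.00238). Bnip3 fell to 9.35 ± 0.21 (-1.23, SE 0.20, adjusted p = 0.0356). In all 4 genes no P3 array overlapped an adherent array, which the naming rule required here too. With only the 2 groups in the fit the adjusted p was 0.126 for Clca2 and Pgap6 and 0.564 for Bnip3. For Bnip3 it was also 0.0550 with a fixed block, 0.0724 with a variance trend and 0.0666 with array weights. Over the alternatives other than single arrays left out, it ran from 0.00411 to 0.126 for Clca2 and from 5.74e-05 to 0.126 for Pgap6. For Bnip3 it ran from 0.00461 to 0.564.

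Of the genes called in P3, Clca2 was lost without adherent array 4, 5 or 6 (adjusted p = 0.0770, 0.0850 and 0.0822) and without P3 array 2, 4, 5 or 6 (0.134, 0.103, 0.0700 and 0.123). Trpv3 was lost without adherent array 4 (0.0575) and without P3 array 2, 5 or 6 (0.127, 0.105 and 0.0732). Bnip3 was lost without adherent array 4 or 5 (0.0799 and 0.117) and without P3 array 2, 4, 5 or 6 (0.242, 0.105, 0.0700 and 0.123). In total 5 rows passed, 3 higher and 2 lower, the fifth being the row with 2 symbols also called in P1 (-0.97, adjusted p = 0.00396), and 4 changed at least 2-fold. At an unadjusted p under 0.05 limma gave 1991 rows, 1564 higher and 427 lower. The count of 5 became 247, 13, 11, 3 and 3 without adherent arrays 1, 2, 3, 4 and 5, and 2 without P3 array 2, 5 or 6. The count of 4 with a 2-fold change became 180, 12, 9, 2 and 2 without the same adherent arrays and 1 without the same P3 arrays. Arrays did not overlap in 181 rows higher and 52 lower, 1.00% of rows against 0.952% from chance.

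After quantile normalization, Cxcl2, the casein gene Csn1s2a and the cystine transporter gene Slc7a11 had the largest increases among the named genes called in P3. Cxcl2 rose from 7.68 ± 1.48 (SD, n = 6) to 12.36 ± 1.01 (SD, n = 4), a change of 4.68 (SE 0.96, adjusted p = 0.0214), and Cxcl1, at 10.14 ± 1.28 in adherent cells, rose by 2.86 (SE 0.57, adjusted p = 0.0181). Both encode chemokines that attract neutrophils. Csn1s2a rose from 5.70 ± 0.65 to 10.11 ± 2.46 (4.41, SE 1.08, adjusted p = 0.0486). Slc7a11, the cystine and glutamate antiporter, rose from 8.23 ± 1.59 to 12.23 ± 0.78 and was 16.1-fold higher (4.01, SE 0.91, adjusted p = 0.0382). The liver protein gene Fetub rose by 3.31 (0.028), the interleukin gene Il1f9 by 2.81 (0.0327), Csf3 by 2.03 (SE 0.32, 0.00497) and the ubiquitin ligase gene Rnf144b by 1.97 (0.0445). Over the alternatives the adjusted p ran from 0.0123 to 0.312 for Cxcl2, from 0.0181 to 0.760 for Cxcl1, from 0.0486 to 0.760 for Csn1s2a and from 0.0304 to 0.760 for Slc7a11.

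The largest decrease in P3 after quantile normalization was in the matrix gene Postn, which fell from 8.88 ± 2.20 (SD, n = 6) to 5.08 ± 0.20 (SD, n = 4), a change of -3.80 (SE 0.76, adjusted p = 0.0181). Postn signals ran from 5.42 to 12.04 among adherent arrays as deposited. Muc1 fell to 7.49 ± 0.81 (-2.09, SE 0.29, adjusted p = 0.00233), Ccn1 to 9.17 ± 0.82 (-2.32, SE 0.43, adjusted p = 0.0121) and Pde2a from 9.46 ± 0.22 to 7.49 ± 0.31 (-1.98, SE 0.23, adjusted p = 0.00125). Tnfrsf19, a receptor of the tumour necrosis factor family, fell from 9.26 ± 0.21 to 7.58 ± 0.23 (-1.68, SE 0.20, adjusted p = 0.00132). The proteases Prss22 (-2.24, 0.00481) and Prss23 (-1.83, 0.0258) and the adducin Add3 (-1.93, 0.00233) fell as well. Over the alternatives the adjusted p ran from 0.00174 to 0.981 for Postn, from 0.00144 to 0.933 for Muc1 and from 0.000734 to 0.814 for Tnfrsf19. After quantile normalization 343 rows passed, 215 higher and 128 lower, and 131 changed at least 2-fold. That count became 1086, 225 and 217 without adherent arrays 1, 4 and 5, and 136, 177, 110 and 111 without P3 arrays 2, 4, 5 and 6. In 9 of 100 simulations without differences, and in 14 of 100 with replacement, as many rows passed.

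**Figure D2:**
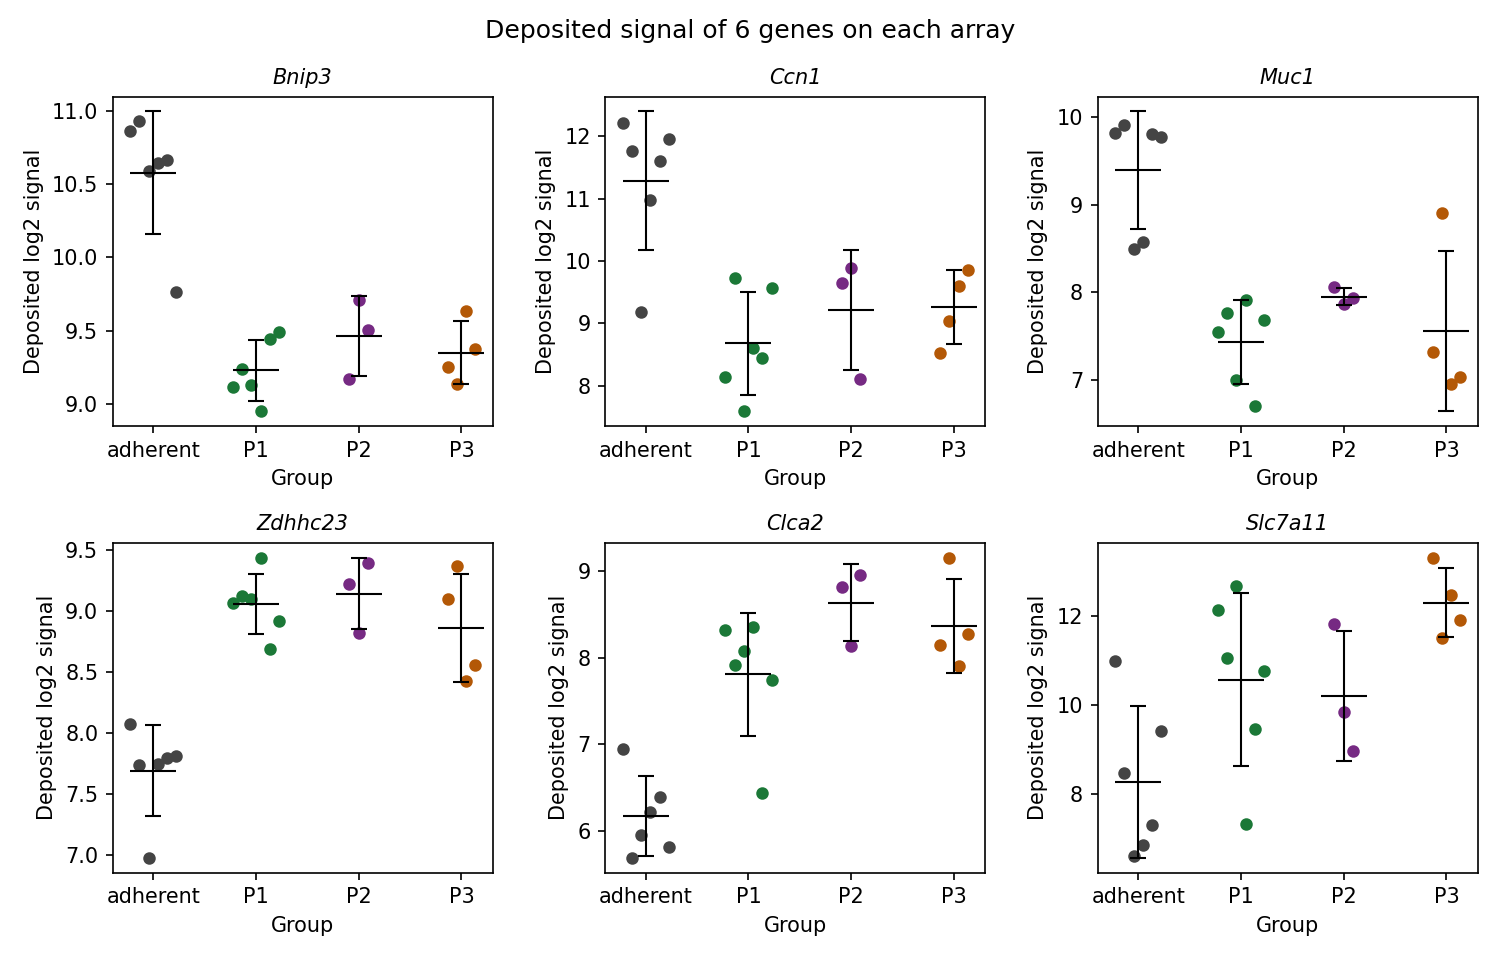
Deposited log2 signal of Bnip3, Ccn1, Muc1, Zdhhc23, Clca2 and Slc7a11 in each adherent, P1, P2 and P3 array; points are arrays and bars are the mean ± SD. Bnip3 averaged 10.58 in adherent cells against 9.23 in P1 and 9.35 in P3, and Clca2 averaged 6.17 in adherent cells against 8.37 in P3.

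Of the 33 gene lists, 16 were called in P1 (7 up and 9 down), 14 in P2 (6 up and 8 down) and 17 in P3 (9 up and 8 down) as deposited. With a correlation estimated within each list, 0 were called in any passage, with adjusted p = 0.769 with an estimated correlation as the smallest value. The count became 10 in P1, 9 in P2 and 12 in P3 without adherent array 1. After quantile normalization 13, 10 and 11 lists were called, and 2 in each passage, hypoxia and focal adhesion, also with an estimated correlation. Over all genes and as deposited, 0 members passed in any list but hypoxia, where limma called Bnip3 in P1 and P3, and at an unadjusted p under 0.05 the whole table gave 1886, 1684 and 1991 rows. Counts of members given below are therefore adjusted over the list alone, or over all genes after quantile normalization where named so.

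The list of genes that low oxygen induces was called downward in all 3 passages. Of the 18 measured hypoxia genes 15 were lower in each passage, with a median change of -0.66 in P1 (adjusted p = 6.71e-10), -0.68 in P2 (1.39e-07) and -0.42 in P3 (1.29e-06). In each passage the list had an adjusted p = 0.769 with an estimated correlation as deposited. After quantile normalization the medians were -0.81, -0.72 and -0.61, and the calls held with adjusted p = 0.0130 with an estimated correlation in P1, 0.0130 in P2 and 0.0288 in P3. Adjusted over the list alone, 6, 3 and 3 members fell and 0 rose, and after quantile normalization 4, 0 and 2 fell over all genes. Besides Bnip3 and Ndrg1, these were Ero1a, an oxidase of the endoplasmic reticulum, which fell in P1 (-1.26, SE 0.18, adjusted p = 0.00251) and P3 (-1.14, 0.00949), and the collagen hydroxylase gene P4ha1, which fell by 1.47 in P1 (SE 0.29, adjusted p = 0.0182). Without adherent array 1 the median was -0.43, -0.28 and -0.21, and without P2 array 4 it was -0.44 in P2. Glycolysis genes, 14 measured, had medians of -0.29, 0.15 and -0.14 (adjusted p = 0.0767, 0.950 and 0.210). They were called after quantile normalization in P1 (-0.47, adjusted p = 0.0153, 0.292 with an estimated correlation) and P3 (-0.41, 0.044, 0.367 with an estimated correlation), where Pdk1, which restrains pyruvate oxidation, fell (-1.02, adjusted p = 0.0392, and -1.11, 0.046). As deposited, they were also called without adherent array 3 in P1 (0.00653) and P3 (0.0254) and without P1 array 6 (0.0177).

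The list of targets of YAP and TEAD, which respond to cell spreading, was called downward in each passage. The 15 measured genes had a median of -0.85 in P1 (adjusted p = 1.58e-07), -0.59 in P2 (6.82e-06) and -0.52 in P3 (0.000271), each with adjusted p = 0.769 with an estimated correlation, and 0.288, 0.292 and 0.453 after quantile normalization. Adjusted over the list alone, 4, 1 and 2 members fell and 1, 0 and 0 rose. The medians were -0.38, -0.15 and -0.15 without adherent array 1, and the calls stayed. Besides Ccn1 and Ccn2, the angiomotin gene Amotl2 fell after quantile normalization in P1 (-1.33, SE 0.19, adjusted p = 0.00264) and P3 (-1.23, adjusted p = 0.00947). Focal adhesion and cytoskeleton genes, 22 measured, had medians of -0.19 in P1 (adjusted p = 0.000699), -0.10 in P2 (0.0161) and -0.15 in P3 (0.00618), with adjusted p = 0.769 with an estimated correlation in P1 and P3 and 0.780 in P2. After quantile normalization the medians were -0.36, -0.32 and -0.37, with adjusted p = 0.0287, 0.0288 and 0.0409 with an estimated correlation, and 5, 2 and 3 members fell over all genes. Talin, Tln1, fell in P1 (-0.84, SE 0.09, adjusted p = 0.00039), P2 (-0.84, SE 0.11, 0.00508) and P3 (-0.75, 0.00232), and the integrin gene Itga3 fell in P1 (-1.22, SE 0.19, 0.00404) and P3 (-1.22, 0.00883). Calponin 2, Cnn2, fell in P1 (-0.69, 0.036) and P3 (-0.89, 0.0164), and alpha-actinin 1, Actn1, in P1 (-0.64, 0.0371). As deposited the focal adhesion call was lost in P2 without adherent array 1 (0.06, adjusted p = 0.262) or 2 (0.04, 0.203) and P2 array 4 (-0.05, 0.0723), and in P3 without adherent array 1 (0.02, 0.201) or 2 (-0.05, 0.0984). The P1 call stayed, but its median was 0.000202 without adherent array 1 (adjusted p = 0.0470), -0.07 without array 2, -0.44 without array 3 and -0.29 without array 4. In P2 it was -0.33, -0.15 and -0.03 without adherent arrays 3, 4 and 5 and -0.15 without P2 array 2, and in P3 it was -0.34 without adherent array 3 and -0.24 and -0.07 without P3 arrays 2 and 6.

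The lists of matrix genes and of fibroblast and leukocyte markers were called downward in each passage as deposited, and mesenchymal genes in P1 and P2. The 23 extracellular matrix genes had medians of -0.32 in P1 (adjusted p = 0.000128), -0.20 in P2 (0.000553) and -0.16 in P3 (0.00395), each with adjusted p = 0.769 with an estimated correlation. Mesenchymal genes, 18 measured, had medians of -0.44 (adjusted p = 0.00141) and -0.25 (0.00621), each with adjusted p = 0.769 with an estimated correlation, and -0.30 in P3 (0.0739, not called). In limma, 0 members of either list passed when adjusted over the list alone. After quantile normalization 1 mesenchymal member rose and 1 fell over all genes in P1, the latter being Vim, the intermediate filament vimentin (-1.70, SE 0.42, adjusted p = 0.0484, and from 0.0220 to 0.929 over the alternatives). The 15 fibroblast markers had medians of -0.80 (1.58e-07), -0.76 (2.84e-07) and -0.80 (5.29e-06), each with adjusted p = 0.769 with an estimated correlation. Among them, Postn fell in each passage when adjusted over the list alone, and 0 others did. The 15 leukocyte markers had medians of -0.12 (0.00618), -0.04 (0.0433) and -0.08 (0.00878), each with adjusted p = 0.769 with an estimated correlation. After quantile normalization the leukocyte medians were -0.09 (adjusted p = 0.122), -0.05 (0.461) and -0.05 (0.194). With the experiment number as a block, the leukocyte call in P2 was lost (0.02, adjusted p = 0.340).

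Most of these calls were lost without adherent array 1. Without that array the extracellular matrix median was -0.05 in P1 (adjusted p = 0.0557), 0.05 in P2 (0.197) and 0.02 in P3 (0.433), and the mesenchymal median was 0.01 in P1 (0.469) and 0.14 in P2 (0.980). The fibroblast calls stayed without it, but their medians were -0.08, -0.06 and -0.04. Leukocyte medians were -0.04 in P1 without adherent array 1 and -0.19, -0.12 and -0.14 without array 2, and -0.02 in P2 without array 3. They were -0.12, -0.07 and -0.07 without P2 arrays 1, 2 and 4 and -0.03 and -0.16 without P3 arrays 2 and 6. In P2 the extracellular matrix median was -0.32 without adherent array 3 and -0.31 and -0.12 without P2 arrays 1 and 4, and in P3 it was -0.31 without adherent array 3 and -0.24 without P3 array 4. The mesenchymal median in P2 was -0.46, -0.37 and -0.43 without adherent arrays 3, 5 and 6. Mesenchymal genes were called in P3 without adherent array 2, 3, 4, 5 or 6 (0.0496, 0.0302, 0.0291, 0.0371 and 0.0235). Leukocyte markers were lost in P1 without adherent array 3 (0.0859). In P2 they were lost without adherent array 1, 3, 4 or 6 (0.201, 0.200, 0.0873 and 0.0534) and without P2 array 2 or 4 (0.0768 and 0.0856). In P3 they were lost without adherent array 1 or 3 (0.0585 and 0.0733) and without P3 array 2 (0.0795). Without adherent arrays 1 and 3 together, the fibroblast median was -0.04 in P1 (adjusted p = 0.0487), -0.00 in P2 (0.0898) and -0.02 in P3 (0.262). Endothelial markers, 14 measured, had medians of -0.05, -0.02 and -0.02 (adjusted p = 0.160, 0.160 and 0.266) and were called only without adherent array 2 (0.00393, 0.00834 and 0.0142). Adipocyte markers, 10 measured, had medians of -0.09, -0.06 and -0.06 (adjusted p = 0.173, 0.631 and 0.427).

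The epithelial junction list was called upward and the basal list downward in each passage as deposited. The 20 junction genes had medians of 0.33 in P1 (adjusted p = 0.000753), 0.39 in P2 (0.00137) and 0.32 in P3 (0.000553), each with adjusted p = 0.769 with an estimated correlation, and 2, 0 and 4 members rose when adjusted over the list alone. Cldn1 rose by 1.56 in P3 after quantile normalization (adjusted p = 0.00427). The list was not called after quantile normalization (0.15, 0.09 and 0.11, adjusted p = 0.126, 0.398 and 0.171), nor in P2 without adherent array 1 (0.0557). Without adherent array 3 its medians were 0.17, 0.22 and 0.21. Basal genes, 16 measured, had medians of -0.18 (0.00778), -0.15 (0.00618) and -0.16 (0.0371), each with adjusted p = 0.769 with an estimated correlation, and 0 members passed over the list alone in limma. After quantile normalization the basal list was not called (-0.21, -0.13 and -0.13, adjusted p = 0.0800, 0.0700 and 0.156). It was also lost without adherent array 1 (-0.02, -0.01 and 0.04, adjusted p = 0.233, 0.201 and 0.633), and in P3 without adherent array 3 or 6 (0.0859 and 0.0527) or P3 array 4 (0.0813). Its median was -0.36 in P1 and -0.25 in P2 without adherent array 4, and -0.23 and -0.10 in P2 without adherent array 2 and P2 array 4.

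Of the luminal, stem and milk lists, milk genes in P3 were called as deposited. Luminal genes, 16 measured, had medians of -0.04, 0.02 and -0.02 (adjusted p = 0.116, 0.145 and 0.0767), with 1 member, Muc1, lower in each passage over the list alone. The luminal factor gene Elf3 fell after quantile normalization in P1 (-0.80, adjusted p = 0.0404) and P3 (-0.86, 0.0477). The luminal list was called in P2 after quantile normalization (-0.09, adjusted p = 0.0466, 0.292 with an estimated correlation) and without adherent array 3 (0.0495), and in P3 without adherent array 3 (0.0270) or P3 array 4 (0.0247). Stem and progenitor genes, 22 measured, had medians of 0.00, 0.15 and 0.06 (adjusted p = 0.941, 0.526 and 0.877), with 1, 0 and 1 member higher over the list alone. The Polycomb gene Bmi1 rose after quantile normalization in P1 (0.71, SE 0.12, adjusted p = 0.0054) and P3 (0.80, SE 0.13, 0.00681). Milk and secretory genes, 14 measured, had medians of 0.18 (0.166), 0.41 (0.0582) and 0.27 (0.00274), the last with adjusted p = 0.769 with an estimated correlation, and 1, 2 and 4 members rose over the list alone. After quantile normalization 1, 0 and 3 rose over all genes. Besides Csn1s2a, the protease inhibitor Slpi rose by 1.54 in P3 (0.0400) and the whey protein gene Wfdc18 by 0.68 in P1 (0.0351) and 0.74 in P3 (0.0393) after quantile normalization. Milk genes were also called in P2 without adherent array 6 (0.0256) or P2 array 4 (0.0281), and their P3 median was 0.47 without P3 array 5.

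The lists of targets of p53 and of the antioxidant factor NRF2 were called upward in every passage as deposited. The 18 p53 targets had medians of 0.58 in P1 (adjusted p = 0.000553), 0.90 in P2 (3.69e-06) and 1.03 in P3 (1.02e-06), each with adjusted p = 0.769 with an estimated correlation. Of these, 0, 8 and 11 rose and 0 fell when adjusted over the list alone. After quantile normalization 3 rose over all genes in P3, the kinase gene Plk2 (1.41, adjusted p = 0.0445), the death receptor gene Fas (0.95, SE 0.16, 0.00883) and the cyclin gene Ccng1 (0.85, 0.0476). The cell cycle inhibitor gene Cdkn1a, higher by 1.23 in P2 as deposited, rose over the list alone but not over all genes (adjusted p = 0.564). The 19 NRF2 targets had medians of 0.44 (0.00082), 0.45 (0.0267) and 0.70 (4.77e-06), each with adjusted p = 0.769 with an estimated correlation, and 4, 1 and 7 members rose over the list alone. Gclc, the rate-limiting enzyme of glutathione synthesis, rose by 1.87 in P3 after quantile normalization (SE 0.34, adjusted p = 0.0121), as did Slc7a11. Ephx1 differed by 1.29 in P3 as deposited (adjusted p = 0.177). The NRF2 call in P2 was lost after quantile normalization (0.19, 0.362), and without adherent array 2 or 4 (0.0607 and 0.0547) or P2 array 1 (0.113). The NRF2 median was 0.25 in P1 without adherent array 3 and 0.44 in P3 without P3 array 2.

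The oxidative phosphorylation and cholesterol synthesis lists were called upward in each passage as deposited. The 18 oxidative phosphorylation genes had medians of 0.36 in P1 (adjusted p = 4.18e-05), 0.54 in P2 (1.58e-07) and 0.31 in P3 (0.00159), each with adjusted p = 0.769 with an estimated correlation, and 1, 3 and 1 members rose over the list alone. Ndufs1, a subunit of complex I, rose after quantile normalization in P1 (0.72, SE 0.12, adjusted p = 0.00702), P2 (0.86, 0.0314) and P3 (0.78, 0.00949). The P3 call of this list was lost after quantile normalization (0.11, 0.119). Without adherent array 3 the median was 0.16 in P1 and 0.14 in P3, and the calls stayed. The 18 cholesterol synthesis genes had medians of 0.38 (0.00164), 0.49 (0.00878) and 0.42 (0.00392), each with adjusted p = 0.769 with an estimated correlation, and 0, 0 and 3 members rose over the list alone. Msmo1 rose by 0.82 in P3 after quantile normalization (adjusted p = 0.0441), and Hsd17b7 differed by 0.95 in P1 and 1.25 in P3 as deposited (0.415 and 0.260). The cholesterol call was lost after quantile normalization in P2 (0.25, 0.218) and P3 (0.22, 0.0523), and in P2 with the experiment number as a block (0.22, 0.214). It was also lost without adherent array 1 (0.118, 0.233 and 0.175), and in P2 without adherent array 3 (0.0859) or P2 array 4 (0.146). Cholesterol medians were 0.12, 0.22 and 0.10 without adherent array 3. Fatty acid synthesis genes, 17 measured, had medians of 0.13, 0.05 and -0.08 (0.507, 0.941 and 0.670), and fatty acid oxidation genes, 15 measured, had 0.05, 0.19 and -0.05 (0.877, 0.651 and 0.877). Both of these were negative in all 3 passages after quantile normalization, and 1 oxidation gene rose and 1 fell over all genes in P1.

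The list of the unfolded protein response was called upward in each passage as deposited. The 18 measured had medians of 0.27 in P1 (adjusted p = 0.00595), 0.52 in P2 (0.000138) and 0.47 in P3 (0.00022), each with adjusted p = 0.769 with an estimated correlation, and 0, 0 and 1 members rose over the list alone. The co-chaperone gene Dnajb11 rose after quantile normalization in P1 (0.63, adjusted p = 0.0208) and P3 (0.78, 0.0121). The P1 call was lost after quantile normalization (0.10, 0.287), with the interquartile range as a covariate (0.05, 0.172) and without adherent array 3 (0.01, 0.227), which gave 0.29 in P2 and 0.26 in P3, and the P1 median was 0.46 without adherent array 1. Amino acid stress genes under ATF4, 20 measured, had medians of -0.02, 0.12 and 0.13 (0.219, 0.687 and 0.687), and P1 was called after quantile normalization (-0.13, 0.044, 0.754 with an estimated correlation) or without adherent array 4 (-0.14, 0.00756). Lysosome and autophagy genes, 23 measured, had medians of 0.16 (0.385), 0.37 (0.0954) and 0.43 (0.0073), the last with adjusted p = 0.769 with an estimated correlation, and 1, 0 and 3 members rose over the list alone. After quantile normalization 0 lysosome members rose and 2 fell over all genes in P1, and 1 rose and 1 fell in P3. The P3 lysosome call was lost after quantile normalization (0.13, 0.287) and without adherent array 3 (0.17, 0.0673) or 4 (0.0520), and P2 was called without adherent array 1 or 5 or P2 array 1 (0.0237, 0.0243 and 0.0374).

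Inflammatory genes under NFkB, 25 measured, had medians of 0.14 (adjusted p = 0.466), 0.06 (0.926) and 0.27 (0.0334), the last with adjusted p = 0.769 with an estimated correlation. Adjusted over the list alone 3, 1 and 6 members rose, and after quantile normalization Csf3, Cxcl1 and Cxcl2 rose over all genes in P3. The call was lost after quantile normalization (0.25, 0.0844), without adherent array 4 or 5 (0.194 and 0.119) and without P3 array 2 or 6 (0.0635 and 0.0745), and P1 was called without P1 array 4 (0.0353). The P3 median was 0.73, 0.13 and 0.09 without adherent arrays 1, 3 and 4. Interferon-stimulated genes, 19 measured, had a median of -0.39 in P1 (0.00132), with adjusted p = 0.769 with an estimated correlation, and 0.15 in P2 (0.890) and -0.21 in P3 (0.0925). In limma, 0 of them passed when adjusted over the list alone. The P1 call was lost without adherent array 1 (0.04, 0.469), which also gave an upward call in P2 (0.63, 0.0214), and P3 was called without adherent array 4 or 5 or P3 array 4 (0.00515, 0.0106 and 0.000329). The P1 median was -0.63 and -0.58 without adherent arrays 4 and 5. MHC class I genes, 13 measured, had medians of -0.09, 0.18 and 0.16 (0.436, 0.877 and 0.941).

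The cell cycle list was called upward in P1 and downward in P3 as deposited. The 26 measured had a median of 0.44 in P1 (adjusted p = 0.0424, and adjusted p = 0.884 with an estimated correlation), with 25 members higher, 0.12 in P2 (0.526) and -0.48 in P3 (0.00076, and adjusted p = 0.769 with an estimated correlation), with 20 members lower. Adjusted over the list alone 0 members passed in limma. The S phase cyclin gene Ccne2 differed by 1.25 in P1 (adjusted p = 0.595) and the topoisomerase gene Top2a by -1.32 in P3 (0.646). The P1 call was lost after quantile normalization (0.36, 0.118), with the interquartile range as a covariate (0.12, 0.547), without adherent arrays 1 and 3 together (-0.02, 0.915), without adherent array 1, 3 or 6 (0.270, 0.289 and 0.161) and without P1 array 1, 2, 3 or 4 (0.409, 0.320, 0.189 and 0.185). Its median was 0.17 without adherent array 3 and 0.25, 0.25, 0.79 and 0.78 without P1 arrays 1, 2, 5 and 6. In P3 it was -0.75 without adherent array 3 and -0.88 and -0.23 without P3 arrays 2 and 6. With the experiment number as a block, P2 was called (-0.48, 9.86e-05), as it was with the covariate (-0.42, 0.0294) and without adherent arrays 1 and 3 (-0.29, 0.0325), and after quantile normalization its median was -0.08.

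Signalling lists were not called in any passage as deposited. ErbB family genes, 13 measured, had medians of -0.04, 0.12 and -0.06 (adjusted p = 0.666, 0.774 and 0.872), and 1 member fell over all genes in P1 after quantile normalization. Notch genes, 21 measured, had 0.02, 0.15 and 0.16 (0.877, 0.267 and 0.248), and Wnt genes, 27 measured, had -0.00, 0.11 and 0.01 (0.200, 0.612 and 0.666), with P1 called without adherent array 3 (-0.06, 0.0381) and without adherent arrays 1 and 3 together (-0.03, 0.0257). Immediate early genes, which serum induces, had 0.02, 0.20 and 0.32 over 21 measured genes (0.877, 0.326 and 0.447), among which the stress gene Ier3 rose after quantile normalization in P1 (0.52, adjusted p = 0.0251) and P3 (0.65, adjusted p = 0.0128). The list of Slc7a11 and Tenm4, taken from later work of the same group and not independent evidence, had medians of 1.01, 0.84 and 1.89 (0.821, 0.961 and 0.427), and Slc7a11 rose over the list alone in P1 and P3. The means of the lists per array, compared by an exact permutation test, gave 2, 1 and 3 lists at an unadjusted p under 0.05 in P1, P2 and P3. None passed after adjustment, with smallest adjusted p values of 0.214, 0.707 and 0.236. After quantile normalization 9, 5 and 8 lists had an unadjusted p under 0.05, and 0 passed (smallest adjusted p = 0.0673, 0.10 and 0.0673).

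**Figure D3:**
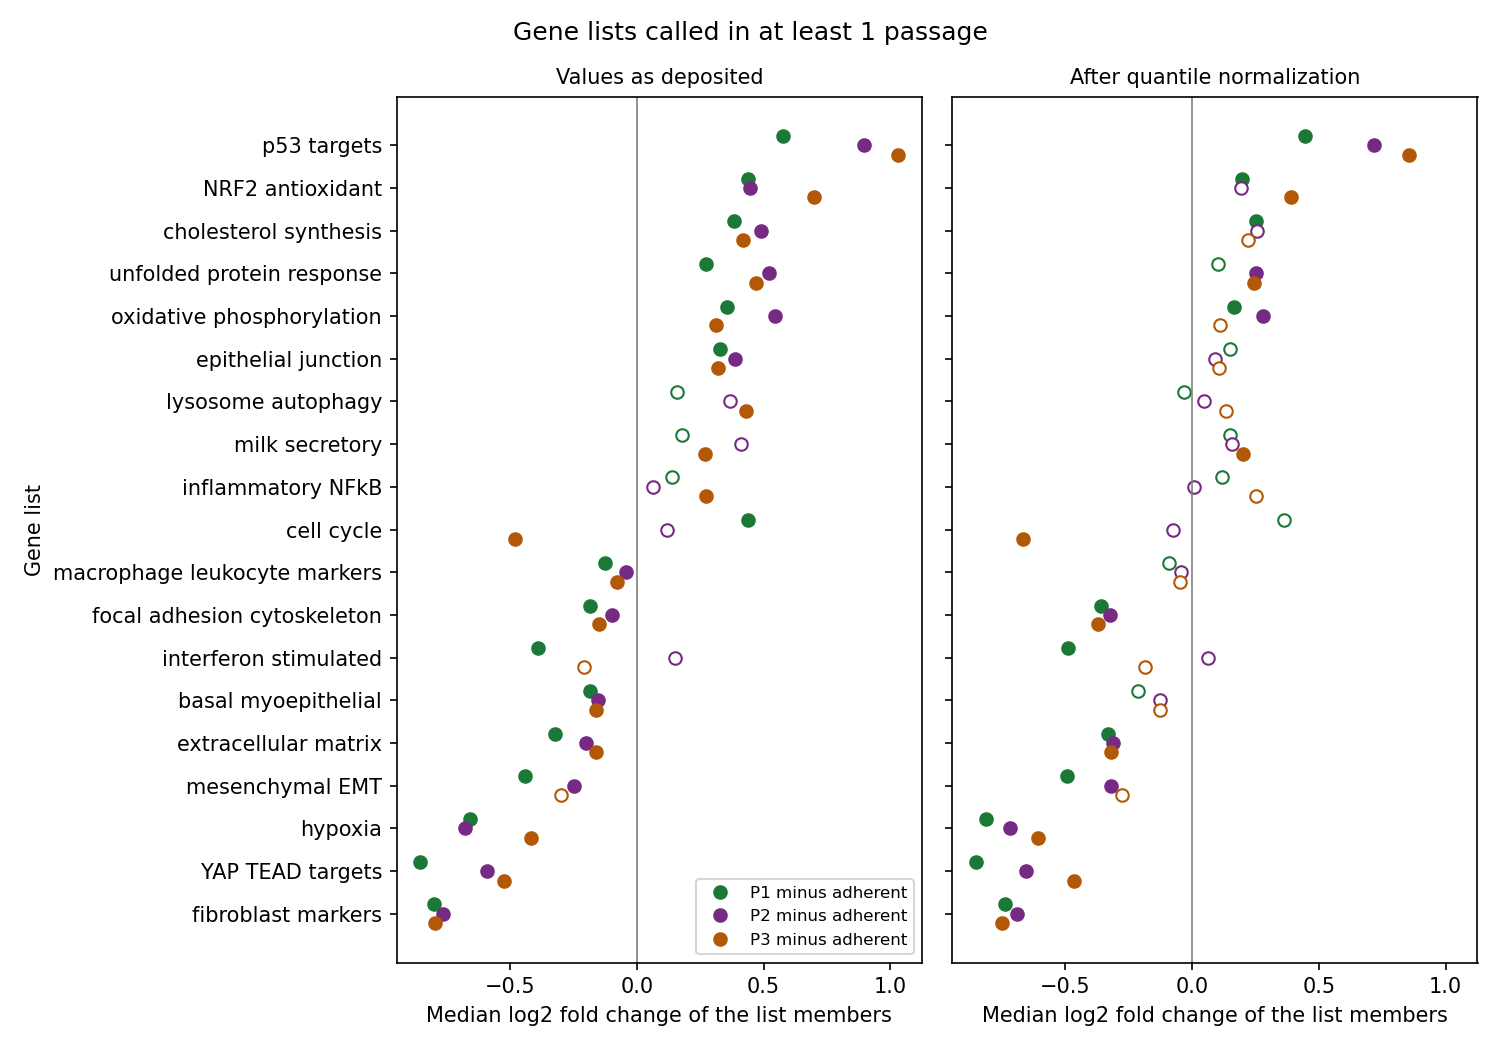
Median log2 fold change against adherent cells of the members of each list called in at least 1 passage, for P1, P2 and P3, as deposited (left) and after quantile normalization (right); filled points passed an adjusted p of 0.05 with a preset correlation and open points did not. Hypoxia medians were -0.66, -0.68 and -0.42 as deposited and -0.81, -0.72 and -0.61 after quantile normalization, and the cell cycle median in P2 turned from 0.12 to -0.08.

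Of the genes reported whatever their result, none passed as deposited. Erbb2 is the mouse counterpart of the activated rat ErbB2 of these cells, and whether its row also detects the rat transcript was not tested. The Erbb2 signal was 10.78 ± 0.52 in adherent cells (SD, n = 6), 11.16 ± 0.25 in P1 (n = 6), 11.46 ± 0.15 in P2 (n = 3) and 11.20 ± 0.46 in P3 (n = 4). It differed by 0.38, 0.68 and 0.42 (adjusted p = 0.692, 0.671 and 0.659). Slc7a11 differed by 2.29, 1.93 and 4.03 (0.522, 0.694 and 0.185), with P1 arrays between 7.34 and 12.67. The teneurin gene Tenm4 differed by -0.28, -0.26 and -0.24 (0.770, 0.797 and 0.798). The adhesion receptors Cd44 (0.62, 0.59 and 0.80, adjusted p = 0.596, 0.696 and 0.518) and Itga6 (0.14, 0.25 and 0.17, adjusted p = 0.903, 0.799 and 0.868) mark progenitor-rich fractions of the mammary gland. The Itga6 differences were -0.06, -0.04 and -0.09 after quantile normalization. The basal keratin Krt14 differed by -0.31, -0.32 and -0.25 (0.522, 0.690 and 0.627), Vim by -1.45, -1.01 and -1.55 (0.495, 0.710 and 0.493) and Cdh1, E-cadherin, by 0.25, 0.29 and 0.27 (0.766, 0.754 and 0.743).

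The series text describes a search for splicing events shared by the 3 passages, at exon level. Shared changes were sought here in gene-level signals, which is a different measure. As deposited, 0 rows passed in the same direction in all 3 in limma, where P2 alone had 0 calls and 1684 rows at an unadjusted p under 0.05. The count became 24 without adherent array 1 and 1 without adherent array 6 or P1 array 5. After quantile normalization 37 rows did, 19 higher and 18 lower. Csf3, Zdhhc23, Arnt2 and Pcdhb17 rose and Ccn1, Muc1, Pde2a, Add3 and Bhlhe41 fell in each passage. The count became 302 and 14 without adherent arrays 1 and 5, and 19 and 13 without P1 arrays 1 and 2. It became 3, 5 and 1 without P2 arrays 1, 2 and 4, and 22 and 10 without P3 arrays 2 and 6. The passages share their adherent arrays, so calls overlap even where no gene differs: simulations with shared adherent arrays gave a mean of 23.1 such rows, and 5 of 100 gave as many as 37. With arrays drawn with replacement, the mean was 72.7 and 35 of 100 gave as many. The highest simulated counts were 1100, and 1643 with replacement. P1 and P3 shared 202 rows, against a simulated mean of 117 (5 of 100 as many, and 16 of 100 with replacement). For this pair the simulated median was 0 in both kinds of simulation, and the highest counts were 6390, and 3439 with replacement. A few very large draws thus raised the means.

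No gene was called between passages in the limma fit of the deposited values. Between P2 and P1, P3 and P1, and P3 and P2, limma called 0 rows. At an unadjusted p under 0.05 it gave 182, 220 and 219 rows, or 0.783%, 0.947% and 0.942% of rows. These shares are below what that threshold gives where no gene differs. All groups shared 1 residual variance per row, and the adherent variance was 3.34 times that within P1. The errors between passages may therefore be too large, so 0 calls do not show that the passages are alike. By the same pooling, the errors of P1 and P3 against adherent cells may be too small, so calls there may be too many. Arrays did not overlap in 1.64%, 0.482% and 2.69% of rows, against 2.38%, 0.952% and 5.71% from chance. With array weights 4 rows passed between P2 and P1. Lists of genes differed between passages only with the preset correlation. The cell cycle list had a median difference of -0.82 between P3 and P1 (adjusted p = 1.68e-21), -0.32 between P2 and P1 (4.72e-06) and -0.58 between P3 and P2 (3.34e-05). For p53 targets it was 0.31 between P2 and P1 (0.00475) and 0.35 between P3 and P1 (0.000738). It was 0.24 for NRF2 targets between P3 and P1 (0.00518) and 0.54 for interferon-stimulated genes between P2 and P1 (4.72e-06). These were also called on quantile-normalized values with the preset correlation. None was called with an estimated correlation, where the smallest values were adjusted p = 0.991 with an estimated correlation as deposited and 0.711 after quantile normalization.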

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

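The tests of the spread of the adherent arrays were chosen after the spread had been seen, and the tests of the cell cycle and hypoxia lists were written before their results were seen.

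The adherent arrays varied more than the sphere arrays: the mean variance of a row among the 6 adherent arrays was 3.34 times that within P1. A smooth curve per array, which stands for compression of the whole signal range, removed 35.3% of the squared deviations within the adherent group, between the bounds of 10% and 50% set for no part and a main part, so compression may be part of the cause and stays open. An outlying single array as the whole cause was argued against, since without adherent array 3, the array that mattered most, the ratio was still 2.57. After quantile normalization it was 2.94. The first principal component of the deposited values, the axis along which the 19 arrays differed most, held 46.2% of the variance. Its scores had a Pearson r of -0.985 with the interquartile range, and adherent arrays 3 (141.0) and 1 (-70.7) lay at its ends. That axis thus followed array spread, while what caused the spread stays open. No biological explanation was tested.

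The cell cycle list was lower in P3 than in P1, with a median difference of -0.82. With the interquartile range of each array as a covariate the difference was -0.91 (SE of the list mean 0.47). With single arrays left out it ran from -1.29 (without P3 array 2) to -0.59 (without P3 array 6). Neither array spread nor a single array could be excluded against that error. Over the 4 experiments that hold both passages it was -0.49 (SE 0.34), and the list was lower in 3 of the 4. The design gives passage as a biological explanation, and all of these stay open. With an estimated correlation the smallest adjusted p among lists between passages was 0.991 as deposited and 0.711 after quantile normalization.

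The hypoxia list was lower than in adherent cells in every passage, with medians of -0.66, -0.68 and -0.42. Array spread as the whole cause was argued against, since the highest median with the interquartile range as a covariate was -0.61. Expression level of its members was also argued against, since in 0 percent of 10000 random lists matched on mean expression was the median as low. Without adherent array 1 the highest median was -0.21, so that array may carry part of the difference and this stays open. Growth as spheres remains a possible biological explanation, to which these tests do not speak beyond these values.

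Among the named genes, 18 of 231 tests of a group of 4 or more arrays put 1 array far from the others by Dixon's criterion, where chance flags about 1 in 20 groups and so 11.6 in these tests. In adherent array 1, Pgap6 was at 7.71 and Tenm4 at 8.10. In adherent array 2, Gpx2 was at 7.04. In adherent array 3, Zdhhc23 was at 6.98, Itga6 at 10.29 and Sqle at 7.34. In adherent array 6, Bnip3 was at 9.76, while the other adherent arrays had 10.59 to 10.93. In P1 array 4, Cxcl2 was at 7.44 and Rnf144b at 7.93. In P1 array 5, Cdr2 was at 8.46, Clca2 at 6.44, Ndufs1 at 8.78 and Dnajb11 at 9.06. In P1 array 6, Pcdhb17 was at 8.25, Lrp1 at 7.58 and Csn1s2a at 11.66. In P3 array 4, Prss22 was at 9.05 and Ephx1 at 12.75.

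Some lists differed between passages when tested directly with the preset correlation, and none did with an estimated correlation, as deposited or after quantile normalization. On quantile-normalized values the differences of immediate early (0.11, adjusted p = 0.0868), Notch (0.08, 0.224) and unfolded protein response genes (0.15, 0.142) between P2 and P1 and of Notch genes between P3 and P1 (0.06, 0.0635) were not called. Between P2 and P1 the deposited differences in median were -0.32 for cell cycle, 0.21 for glycolysis, 0.21 for immediate early genes, 0.16 for Notch, 0.54 for interferon-stimulated genes, 0.25 for the unfolded protein response, 0.31 for p53 targets and 0.20 for oxidative phosphorylation. Between P3 and P1 they were 0.13 for milk genes, -0.82 for cell cycle, 0.13 for Notch, 0.14 for the unfolded protein response, 0.15 for ATF4 genes, 0.24 for NRF2 targets, 0.35 for p53 targets, 0.24 for NFkB genes and 0.20 for lysosome genes. Between P3 and P2 they were -0.58 for cell cycle, -0.32 for interferon-stimulated genes, 0.26 for NRF2 targets, 0.33 for NFkB genes and -0.20 for oxidative phosphorylation.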

How the results depend on the processing

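The interquartile range as a covariate, adherent arrays 1 and 3 left out together, and the settings that join quantile normalization with another choice were chosen after the data were seen, and the exact permutation tests were too. Of the alternatives for named genes, those with 1 array left out kept the side of the threshold in 2225 values, passed it in 72, lost it in 28 and reversed in 0. Other settings kept it in 2142, passed it in 537, lost it in 9 and reversed in 0. For the lists, left-out arrays kept 947, gained 25, lost 49 and reversed 2. Other settings kept 672 list results, gained 21, lost 197 and reversed 1, where reversed refers to the direction of the test. A reversal was counted only where the reported or the alternative value was called. Genes and lists called in neither counted as kept whatever their sign, so these counts do not show that directions were kept. Quantile normalization and the covariate called 303 of 363, 36 of 41 and 249 of 343 of the same rows in P1, P2 and P3, all in the same direction. Array weights called 270, 35 and 209 of those quantile-normalized calls. Of the 7, 1 and 15 rows called with the fixed block, 7, 0 and 13 were among them. The arrays carry no signal over background in the table used, so what background limits was not measured. Exon-level splicing was not analysed here.

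The count of rows in P1, 4 as deposited, was 7 with a fixed block, 12 with a random block, 363 after quantile normalization, 124 with median centring, 14 above the 50th percentile, 1374 with array weights, 636 with the covariate, 73 without adherent arrays 1 and 3, 0 with only the 2 groups and 2 at an adjusted p under 0.01. In P2, 0 as deposited, it was 1 with a fixed block, 41 after quantile normalization, 8 with median centring, 1 above the 50th percentile, 2797 with weights, 168 with the covariate and 7 without adherent arrays 1 and 3. In P3, 5 as deposited, it was 15, 24, 343, 104, 14, 651, 438, 177, 1 and 2 under the settings listed for P1. Between P2 and P1 weights gave 4. With 1 array left out the counts ran from 2 to 138 in P1, from 0 to 27 in P2, from 2 to 247 in P3 and stayed at 0 between passages.

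With a 2-fold change, the count in P1 was 6 with a fixed block, 10 with a random block, 106 after quantile normalization, 69 with median centring, 13 above the 50th percentile, 291 with weights and 0 with only the 2 groups. In P2 it was 1 with a fixed block, 31 after quantile normalization, 8 with median centring, 1 above the 50th percentile and 501 with weights. In P3 it was 14, 21, 131, 76, 13, 255 and 1 under the settings listed for P1. With 1 array left out it ran from 1 to 94, from 0 to 25 and from 1 to 180. Rows shared by all 3 passages numbered 1 with a fixed block, 37 after quantile normalization, 8 with median centring, 1 above the 50th percentile and 461 with weights, and from 0 to 24 with 1 array left out.

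On quantile-normalized values, the fixed block gave 675, 42 and 422 in P1, P2 and P3 and 38 shared, and weights gave 944, 625 and 679 in P1, P2 and P3 and 329 shared. Without adherent arrays 1 and 3 they were 963, 323 and 1032, and 284 shared. With 1 array left out they ran from 140 to 1078, from 2 to 339 and from 110 to 1086, and from 1 to 302 shared. Median centring, the percentile filter and only the 2 groups changed the scale, the rows tested or the arrays used. The cause of the other changes was not tested.

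Of the lists, 0 were called in each passage with an estimated correlation and 0 by fry, and 2 in each on quantile-normalized values with an estimated correlation. In P3 11 were called after quantile normalization and 11 without adherent arrays 1 and 3. With 1 array left out 10 to 17 were called in P1, 9 to 15 in P2 and 12 to 18 in P3. The calls lost in no other alternative were 7 of 16 in P1, 5 of 14 in P2 and 7 of 17 in P3. These were hypoxia, YAP targets and p53 targets in each passage, NRF2 targets in P1 and P3, oxidative phosphorylation in P1 and P2, the unfolded protein response in P2 and P3, focal adhesion and fibroblast markers in P1, and milk and cell cycle genes in P3. With the covariate the calls of basal, cholesterol and leukocyte genes were lost in each passage, of cell cycle and unfolded protein response genes in P1, of junction and NRF2 genes in P2, and of NFkB, lysosome and oxidative phosphorylation genes in P3. Without adherent arrays 1 and 3 those of basal, junction, cholesterol, matrix and leukocyte genes were lost in each passage, of mesenchymal genes in P1 and P2, of cell cycle and interferon-stimulated genes in P1, of fibroblast markers in P2 and P3, and of oxidative phosphorylation in P3. Above the 25th percentile cell cycle genes in P1, leukocyte markers in P2 and NFkB genes in P3 were lost. Calls were gained with the covariate for ATF4 genes in P1, cell cycle genes in P2 and interferon-stimulated genes in P3. Without adherent arrays 1 and 3 they were gained for luminal genes in each passage, glycolysis and Wnt genes in P1, and cell cycle and interferon-stimulated genes in P2, and above the 25th percentile for glycolysis in P1, luminal genes in P2 and P3, and mesenchymal and interferon-stimulated genes in P3. Without adherent array 1 the P1 medians of focal adhesion and fibroblast markers were 0.000202 and -0.0763, with the calls kept. Mesenchymal genes in P2 reversed without adherent array 1 (0.14, against -0.46 without adherent array 3 as the lowest). For interferon-stimulated genes in P2, not called as deposited, the direction of the test turned upward without adherent array 1 (0.63, against -0.0895 without adherent array 4 as the lowest) and without adherent arrays 1 and 3 (0.56). Their median of 0.15 stayed positive in both. The cause was not tested.

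Arrays with the same experiment number were correlated above 0.1 in 3 of 6 pairs for adherent and P1 and 2 of 4 for adherent and P3. They were so in 1 of 3 for P1 and P2, 2 of 4 for P1 and P3 and 0 of 2 for P2 and P3. The rule therefore did not treat these groups as paired. The highest correlations were 0.56 for adherent and P1, 0.54 for adherent and P3, 0.51 for P1 and P2 and 0.57 for P1 and P3. Arrays with different numbers were not compared, so a common origin by experiment was neither shown nor excluded. The block changed no other call of a named gene in P2. In P1 it gained glycolysis (-0.29, adjusted p = 0.0192). In P3 it lost Bnip3, basal genes (-0.09, 0.138) and cholesterol synthesis (0.30, 0.0606) and gained glycolysis (-0.23, 0.0118).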

Other observations

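Regroupings of the arrays, overlaps with shared adherent arrays and per-array list means were tests chosen in part after the data were seen, as given in the methods.

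Signals of some named genes varied widely between the arrays of at least 1 group. Csn1s2a, a casein, had 4.82 to 6.46 in adherent arrays, 5.62 to 6.71 in P1 arrays other than replicate 6, which had 11.66, 8.06 to 11.80 in P2 and 7.40 to 13.22 in P3. Postn had 5.42 to 12.04 in adherent arrays and 4.87 to 5.54 in all sphere arrays. Slc7a11 had 7.34 to 12.67 in P1 and 11.51 to 13.31 in P3.

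Of the groupings of the same arrays, each count including the true one, few reached the P1 count of 4 (2 of 100 as large, the highest other 7398), the P1 count of 3 with a 2-fold change (2 of 100, highest 1194), the P1 count of 363 after quantile normalization (2 of 100, highest 2160) or the P3 count of 343 after quantile normalization (3 of 100, highest 911). For the 37 shared rows it was the true grouping alone (1 of 100, highest 0 among the others). Simulations with shared adherent arrays in which no gene differed reached most of these counts more often, and the count of 3 was not compared with them. They gave 4 rows or more in P1 in 8 of 100, 363 in 12, 343 in 9 and 37 shared rows in 5, and with arrays drawn with replacement in 46, 19, 14 and 35 of 100. For 363, 343 and 37, the simulated arrays were not normalized again, so they could differ in distribution as the real ones could not. Arrays drawn with replacement could also repeat within a group, which lowers its spread. These simulations therefore do not decide about those counts. Chance stays open for the 363, 343 and 37 rows, and was not excluded for the 4 rows as deposited. By the regroupings it was not excluded for the lists in P1 (8 of 100, highest 20 against 16), P2 (22 of 84, highest 19 against 14) or P3 (9 of 100, highest 20 against 17). Nor was it excluded for the P2 count of 41 after quantile normalization (6 of 84, highest 4815) or for the P3 counts of 5 (9 of 100, highest 5510) and 4 (9 of 100, highest 1542). The regroupings for P2 did not keep adherent and P2 arrays paired by experiment number. A count of 0 is reached by every regrouping, so the comparison says nothing about chance for P2 (84 of 84, highest 10113), P2 with a 2-fold change (84 of 84, highest 4780), the passages against each other (84 of 84, 100 of 100 and 35 of 35, highest 1, 1 and 0) or the shared rows as deposited (100 of 100, highest 0). The regroupings with the highest counts set adherent arrays 1, 2 and 5 against 3, 4 and 6, and their difference in mean interquartile range was 0.592, 0.856 and 0.639 in P1, P2 and P3, the largest of all drawn, against 0.211, 0.342 and 0.266 for the true groups, which points to a structure among the adherent arrays.

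After quantile normalization, the correlation of the changes of all rows was 0.821 between P1 and P2, 0.818 between P1 and P3 and 0.787 between P2 and P3. The passages share the adherent arrays, and simulations in which no gene differed gave means of 0.676, 0.693 and 0.632, or 0.703, 0.694 and 0.670 with arrays drawn with replacement. With separate adherent arrays for each passage of a pair it averaged 0.258, 0.263 and 0.282. The covariance was 0.0971, 0.0982 and 0.106, against simulated means of 0.0672, 0.0714 and 0.0653, or 0.0461, 0.0476 and 0.0462 with replacement. Pairs of passages called 38 (P1 and P2) and 39 (P2 and P3) of the same rows, against simulated means of 30.4 and 26.3, and 6 of 100 simulations gave as many in each. With arrays drawn with replacement the means were 86.7 and 85.5, and 35 of 100 gave as many in each. The simulated medians were 0 for these pairs in both kinds of simulation. The highest counts were 1129 and 1106, and 1756 and 2226 with replacement. With separate adherent arrays the pairs shared 37.1, 77.8 and 34.0 rows on average, where independent lists of the same sizes would share 3.00, 7.02 and 2.42. Both fits of a pair still held all sphere arrays, and so took much of each row's residual variance from the same arrays. Their calls can therefore overlap without a shared change, and independent lists are not a like reference. With all adherent arrays, independent lists would share 0.324, 2.79 and 0.308.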
